A study of Ettlia oleoabundans with 10 samples.

How the data were processed

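Poly(A)-selected RNA from cultures of Ettlia oleoabundans, a unicellular green alga that stores oil, was sequenced on the Illumina platform. Per the labels' protocols, cells were inoculated at 1000000 cells per ml in a modified Bold Basal Medium with vitamins and were grown on light alone for 6 days at 25 °C under constant light of 22 to 28 µmol photons m-2 s-1. RNA was extracted with hot phenol and selected on oligo-dT beads. The 10 libraries comprised 1 library for each of 10 conditions. A nitrate series covered 0, 0.38, 0.75, 1.5, 3 and 9 mM. A NaCl series covered 42, 75, 150, 300 and 600 mM. The culture with 9 mM nitrate and 42 mM NaCl was the control of both series. The labels of the other NaCl cultures give no nitrate concentration, and those of the other nitrate cultures give no NaCl concentration. Models of all 10 libraries treated each of those cultures as unchanged from the control in the other factor. Light and cell density, which the series title also names, were not analysed here.

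The deposited table gave 1 value for each of 10122 scaffold families in each library. Scaffold families carry numeric identifiers, and the table does not pair them with gene names or descriptions. The values were recorded as signal: the deposited values are expression levels scaled for feature length and library depth by the authors, as judged from the values themselves. They are never negative, have 2 decimals, sum to different totals in each library, and have smallest steps that differ between families. Whether they are FPKM or TPM, and whether a composition scaling was applied, is not given in the sources used here. The submitters' processing notes name Bowtie 0.12.8, RSEM 1.2.0 and edgeR 3.0.8, with no role or order. The reference sequences, the way in which families were formed and any filter on families are not given in the sources used here. A length-scaled value gives no read depth, so no counting interval or detection limit was computed, and a value of 0 is described as listed at 0. Every per-library column of the table was used.

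The test fixed before the data were examined was a count model. Because the values are not counts, the replacement fixed at the same time was used: limma 3.58.1 (R 4.3.3) with an intensity trend in the prior variance, applied to log2(value + 1). Within each series the slope on the rank of the concentration was tested, with 4 residual degrees of freedom for nitrate and 3 for NaCl. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. With 1 library per condition, the spread in these tests is that of single cultures about a straight line over the ranks, so a response that is not linear in rank adds to it, and no comparison of 2 conditions has a test. Families with a mean value of at least 1 over the libraries fitted were tested. This minimum, and the stricter one of 5, were set once the unit was known and replace minimums stated for counts. The slope per step of nitrate limitation was compared with the slope per step of NaCl in 1 model of all 10 libraries with 7 residual degrees of freedom. Steps of the 2 series are not equal stresses, so the difference is per step only. Numbers of families at least 2-fold from the control describe these libraries and have no test. Numbers and shares given as chance are averages over families. Families of a library can move together, so a count can lie far from its chance value without a trend, and the comparison is not a test. Fold changes are on the log2(value + 1) scale, which understates changes of families with low values.

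Because families have no gene names, the rule fixed in advance named 2 rising and 2 falling families per series. These were the ones with the largest fitted change over the concentration range among families with an adjusted p under 0.05 and a mean value of at least 5. Lists of genes for nitrogen assimilation, photosynthesis, lipid and starch metabolism, ion transport, stress proteins and other functions had been fixed before the data were examined. None could be matched to the families, so no list was tested. Families named outside the rule are described as chosen after their values were seen.

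Alternatives were another scaling by median ratios, equal library totals, other filters and pseudocounts, other codings of concentration, omission of the 50 most abundant families, omission of each library in turn, and models of all 10 libraries. Library titles carry a code: 8 libraries are coded c1 to c8, and the libraries of 0.38 mM nitrate and 150 mM NaCl carry codes beginning with RAA. What the codes stand for is not given in the sources used here. Fits without these 2 libraries, or with a term for them, were planned. Fits with a term for the libraries coded c3 to c6 (75, 300 and 600 mM NaCl and 0 mM nitrate), or within sets of codes, were added after the data were seen, as were the sets of families that separate low from high concentrations.

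The trend test was checked on simulated data with known changes. These changes were linear in rank, and the noise was independent between families and libraries, with each family's own spread. Effects shared by many families of a library were not simulated, so the false calls below do not cover them. For the nitrate design, with 8686 families, 37% of 100 families changed 4-fold over the range and 81% of 100 families changed 16-fold were recovered, with 8 false calls. For the NaCl design, with 9255 families, 11% of the families changed 4-fold and 53% of those changed 16-fold were recovered, with 0 false calls.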

Results

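Transcript levels were measured in 10 cultures of the oil-storing green alga Ettlia oleoabundans, 6 with nitrate from 0 to 9 mM and 5 with NaCl from 42 to 600 mM, the control culture (9 mM nitrate, 42 mM NaCl) being shared by both series. Each condition had 1 library, so no value below has a replicate error. The values are length- and depth-scaled expression levels of 10122 scaffold families, and the read depth behind them is unknown. Among families with values between 0.1 and 1.5 in both libraries, the ratio to 75 mM NaCl found most often was 1.71 at 300 mM NaCl (78 of 602 families) and 0.949 at 0 mM nitrate (52 of 519). In the other libraries the ratios found most often were 0.626 to 0.949 and were shared by 8 to 22 families, so no relative depth was taken from them. Library totals ran from 362924 at 0.38 mM nitrate to 695913 at 300 mM NaCl. Between 380 families (75 mM NaCl) and 1263 families (0.38 mM nitrate) were listed at 0. Relative to the control, the median log2 ratio of the 8445 families above 0 in every library was 0.41 at 150 mM NaCl, 0.25 at 300 mM, 0.23 at 75 mM, 0.20 at 0 mM nitrate and 0.10 at 3 mM nitrate. It was between -0.06 and 0.10 in the other libraries.

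The nitrate series addressed how transcript levels follow the nitrate supply. Among families with an adjusted p under 0.05 and a mean value of at least 5, family 720_c0 had the largest fitted rise with nitrate, 10.81 ± 1.55 (SE) on the log2 scale from 0 to 9 mM (limma, adjusted p = 0.0472). Its expression value was 0.39 at 0 mM, 2.34 at 0.38 mM and 15.46 at 0.75 mM, and then 700.98 at 1.5 mM, 1302.98 at 3 mM and 655.22 in the control. Family 0_c0 rose by 8.96 ± 1.28 (limma, adjusted p = 0.0472), from 15.69 at 0 mM to 2731.84 in the control, with 128.99 at 0.75 mM and 2558.57 at 1.5 mM. Family 1084_c0 fell with nitrate, with a fitted change of -8.39 ± 0.91 (limma, adjusted p = 0.0472). Its value was 1298.79 at 0 mM, 258.13 at 0.38 mM, 237.05 at 0.75 mM, 15.92 at 1.5 mM, 4.84 at 3 mM and 5.23 in the control. Family 9662_c0 changed by -4.13 ± 0.53 (limma, adjusted p = 0.0472), from 26.9 at 0 mM to 8.12 at 0.75 mM, 3 at 1.5 mM and 1.4 in the control. In 3 of these 4 families, 720_c0, 0_c0 and 1084_c0, the largest step between neighbouring concentrations on the log2(value + 1) scale lay between 0.75 and 1.5 mM.

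In all, 23 of 8686 families followed the rank of nitrate, of which 13 rose and 10 fell with more nitrate (limma-trend, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 1965 families, where 434 would be expected by chance on average. Because families can move together, this excess is not a test of a trend. With nitrate coded as 2 levels, 0 to 0.75 mM against 1.5 to 9 mM, 460 families passed, 250 higher and 210 lower at the high level. The call count changed when 1 library was left out: it was 0 without the library of 0, 0.38, 1.5, 3 or 9 mM, and 220 without that of 0.75 mM. The smallest adjusted p (limma) with all 6 libraries was 0.0472, so small changes could move every call over the threshold. The fits with 0 calls had 1184 (without 3 mM) to 2464 (without 0.38 mM) families at an unadjusted p under 0.05. The 4 named families lost the call in 11 or 12 of 19 or 20 alternatives each. Over all these alternatives, with the call kept or lost, adjusted p (limma) ran from 0.00241 to 0.843. The fit without 0.38 mM is counted there under both of its names. With 1 library left out, slopes per step were 2.02 to 2.75 for 720_c0 (2.16 in the main fit) and 1.65 to 2.21 for 0_c0 (1.79). They were -1.57 to -1.95 for 1084_c0 (-1.68) and -0.74 to -0.94 for 9662_c0 (-0.83). Scaling by median ratios gave 187 families, 112 rising and 75 falling, and the 4 libraries coded c1, c2, c7 and c8 alone (0.75, 1.5, 3 and 9 mM), a set chosen after the data were seen, gave 0, with 843 at an unadjusted p under 0.05.

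A set of families separated the 3 lower from the 3 higher nitrate concentrations completely. In 99 families the lowest value at 0, 0.38 and 0.75 mM was at least 2-fold above the highest at 1.5, 3 and 9 mM, and in 129 families the reverse held. This grouping of families was chosen after the data were seen. Of the 10 ways to split the 6 libraries 3 against 3, the next highest gave 3 such families. With no minimum fold, 26.8% of families separated these levels, where chance gives 10%. The 99 families had median log2 ratios to the control of 2.57 at 0 mM, 2.23 at 0.38 mM and 1.80 at 0.75 mM, and of -0.02 at 1.5 mM. The 129 families had medians of -2.17, -2.31 and -1.84 at the 3 lower concentrations and of 0.14 at 1.5 mM.

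**Figure D1:**
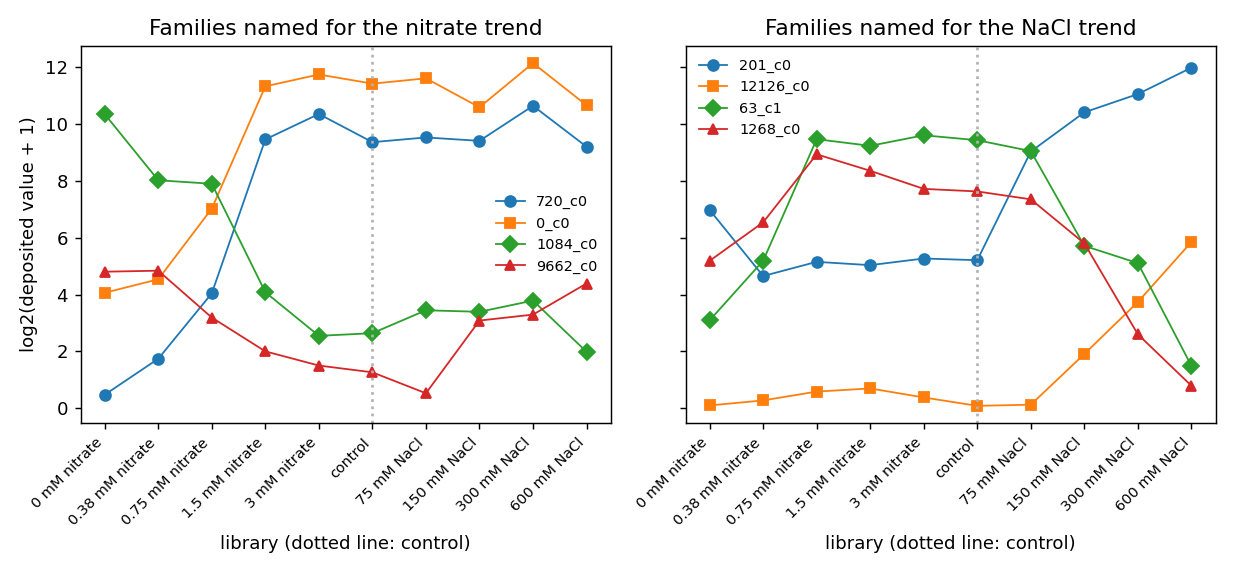
Expression values of the named families, as log2(value + 1), in each of the 10 libraries (1 per condition; the dotted line marks the control). Left, the 4 families named for nitrate, with 720_c0 going from 0.39 at 0 mM to 655.22 in the control; right, the 4 families named for NaCl, with 201_c0 going from 35.93 in the control to 4034.23 at 600 mM NaCl.

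The NaCl series addressed how transcript levels follow salinity. Among families with an adjusted p under 0.05 and a mean value of at least 5, family 201_c0 had the largest fitted rise, 6.23 ± 1.05 (SE) on the log2 scale from 42 to 600 mM (limma, adjusted p = 0.049). Its expression value was 35.93 in the control, 521.1 at 75 mM, 1357.07 at 150 mM, 2118.93 at 300 mM and 4034.23 at 600 mM. The call of 201_c0 was lost without the control, where its slope was 0.95 in place of 1.56 log2 units per step (limma, adjusted p = 0.22). It was also lost in 11 of the other 17 alternatives. The fit without the RAA library is counted there under both of its names. Over all alternatives, with the call kept or lost, adjusted p (limma) ran from 0.00246 to 0.432. With terms for the RAA codes and codes c3 to c6 the slope was 1.11 (limma, adjusted p = 0.0758). The value of 201_c0 at 0 mM nitrate (code c6) was 124.84. Without 600 mM the slope was 1.89 (limma, adjusted p = 0.236). Median-ratio scaling gave 1.54 (limma, adjusted p = 0.0551) and equal library totals 1.48 (limma, adjusted p = 0.065). Family 12126_c0 rose by 6.06 ± 0.79 (limma, adjusted p = 0.0337), with 0.06 in the control, 0.09 at 75 mM, 2.75 at 150 mM, 12.33 at 300 mM and 56.55 at 600 mM. Family 63_c1 fell, with a fitted change of -7.93 ± 0.84 (limma, adjusted p = 0.0211), from 687.63 in the control and 526.87 at 75 mM to 51.37 at 150 mM, 33.39 at 300 mM and 1.81 at 600 mM. Family 1268_c0 changed by -7.37 ± 0.80 (limma, adjusted p = 0.0211), from 196.38 in the control to 161.84 at 75 mM, 54.69 at 150 mM, 5.06 at 300 mM and 0.73 at 600 mM. Both falling families also had low values without nitrate, 7.51 for 63_c1 and 35.33 for 1268_c0 at 0 mM nitrate.

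In all, 79 of 9255 families followed the rank of NaCl, 44 rising and 35 falling (limma-trend, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 1790 families, where 463 would be expected by chance on average, with the same limit as for nitrate. Without the 600 mM library no family passed (limma-trend), with 1109 at an unadjusted p under 0.05. The count was 44 without the control, 13 rising and 31 falling, and 197, 163 and 203 without the libraries of 75, 150 and 300 mM. Median-ratio scaling gave 48 families, 23 rising and 25 falling, equal library totals gave 10, concentration in mM gave 450 (355 rising and 95 falling) and the 3 libraries coded c3 to c5 (75, 300 and 600 mM), chosen after the data were seen, gave 411 with 1 residual degree of freedom.

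At 600 mM the most abundant family was 2_c0, singled out after its values were seen. It took 4.13% of the library total, with a value of 23630.26 against 470.73 in the control, 3769.75 at 75 mM, 14668.21 at 150 mM and 14449.18 at 300 mM. Family 2_c0 was also above the control at 0 mM nitrate (code c6), with 1679.03, and had 297.01 to 461.9 from 0.38 to 3 mM nitrate. A group of 362 families had values at least 10-fold above the control at 600 mM and held 20.4% of that library's total, against 0.662% of the control's total. The corresponding groups held 11% of the total at 300 mM (103 families) and 10.7% at 150 mM (82 families). A set of 191 families had values of at least 5 at 600 mM and under 1 in every other library. Its median value at 600 mM was 6.65, and it made up 0.25% of the library total. Of these 191 families, 124 were above 0 at 75 mM NaCl, 129 at 300 mM NaCl, 57 at 0 mM nitrate and 0 at 150 mM NaCl.

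**Figure D2:**
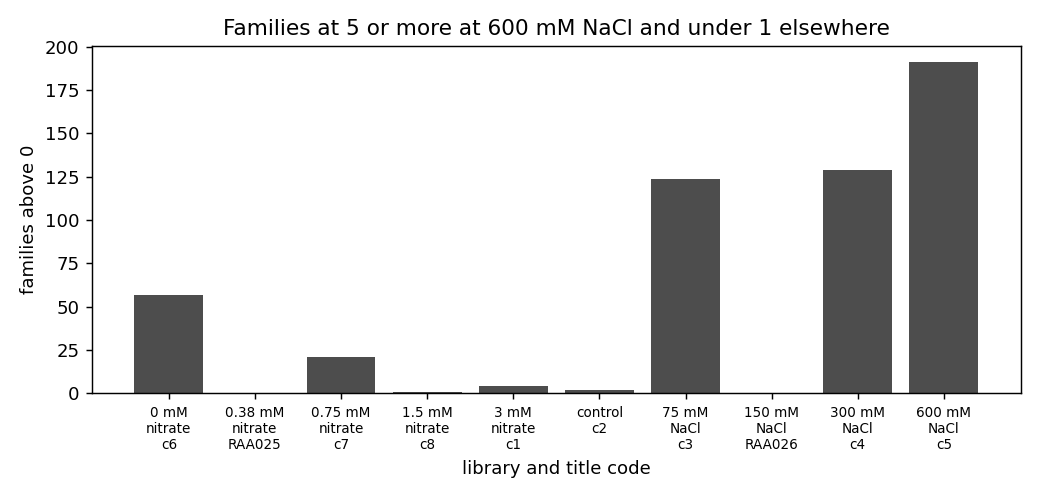
Number of the 191 families with a value of at least 5 at 600 mM NaCl and under 1 elsewhere that were above 0 in each library, with the title code of the library under its condition. The bars stand at 124 for 75 mM, 129 for 300 mM and 57 for 0 mM nitrate, and at 0 for both libraries with RAA codes.

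Against the control, the number of families at least 2-fold away was smallest in the libraries nearest to it in nitrate. Of 9012 families, 45 were higher and 125 lower at 3 mM nitrate, 61 and 346 at 1.5 mM, 646 and 400 at 0.75 mM, 808 and 1347 at 0.38 mM, and 1298 and 1053 at 0 mM. In the NaCl series 662 families were higher and 251 lower at 75 mM, 1566 and 623 at 150 mM, 1385 and 925 at 300 mM, and 1575 and 1222 at 600 mM. These are differences between single libraries, with no replicate check. The balance of higher and lower families depended on scaling. With median-ratio scaling, 827 were higher and 967 lower at 150 mM NaCl, 957 and 1214 at 300 mM, 464 and 414 at 75 mM, 925 and 1291 at 0 mM nitrate, and 29 and 154 at 3 mM nitrate, so that at 150 and 300 mM NaCl and at 0 mM nitrate the larger share changed sides. At 600 mM it gave 1484 and 1353, at 0.38 mM nitrate 956 and 1250, at 0.75 mM 552 and 489, and at 1.5 mM 67 and 349.

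**Figure D3:**
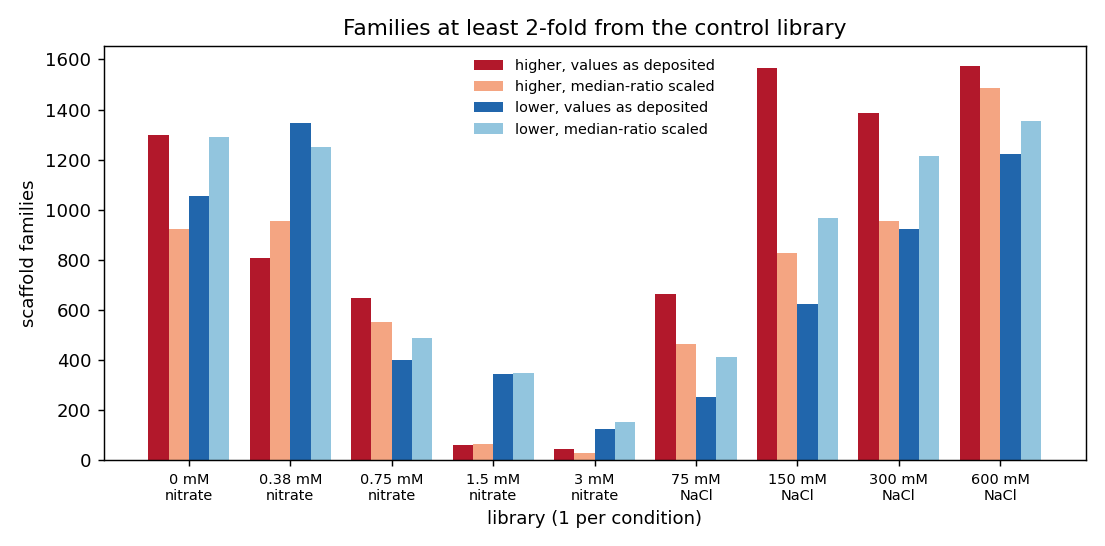
Number of scaffold families at least 2-fold higher (red shades) or lower (blue shades) than the control library in each other library, for the deposited values and after median-ratio scaling. The counts are lowest at 3 mM nitrate (45 higher, 125 lower), and at 150 mM NaCl the 1566 higher families become 827 after scaling.

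Across families, the libraries of 1.5 and 3 mM nitrate had the highest correlation of all pairs (Pearson r = 0.990 of log2 values over 9012 families, which are not independent replicates). The control had r = 0.981 with 3 mM nitrate, 0.922 with 0.75 mM, 0.829 with 0.38 mM, 0.847 with 0 mM, 0.937 with 75 mM NaCl and 0.733 with 600 mM NaCl. The libraries of 0.38 mM nitrate and 150 mM NaCl, the only 2 with RAA codes, departed from their neighbours in the same families. The departure of each library from the mean of its 2 neighbouring concentrations had r = 0.636 between the 2 libraries, and 83 families lay at least 4-fold below the neighbours in both, where 3.37 would be expected if the departures were independent, while 14 lay at least 4-fold above them in both. Family 52_c0, singled out after its values were seen as the most abundant of the 83, had values of 28.16 at 0.38 mM nitrate and 43.32 at 150 mM NaCl. Its value was 579.83 at 0 mM nitrate, 10951.96 at 0.75 mM nitrate, 9716.58 at 75 mM NaCl and 11361.12 at 300 mM NaCl.

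**Figure D4:**
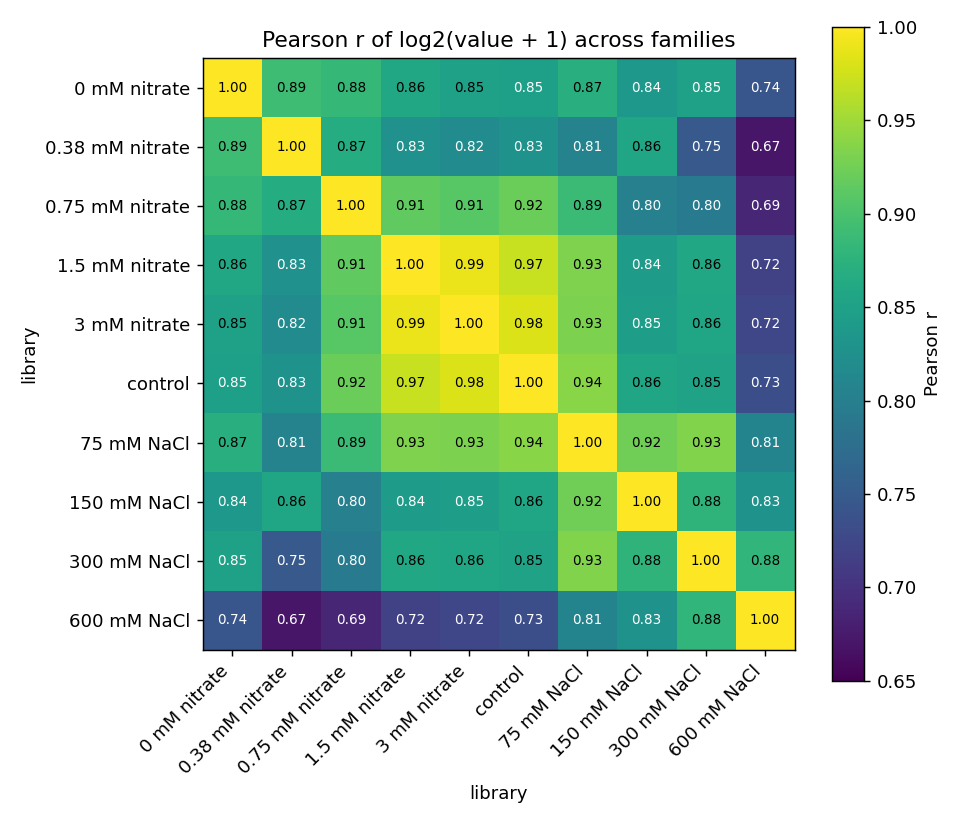
Pearson r of log2(value + 1) over 9012 families for each pair of the 10 libraries, in order of nitrate and then NaCl concentration. The pair of 1.5 and 3 mM nitrate stands highest at 0.990, and the 600 mM NaCl library has 0.733 with the control.

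**Figure D5:**
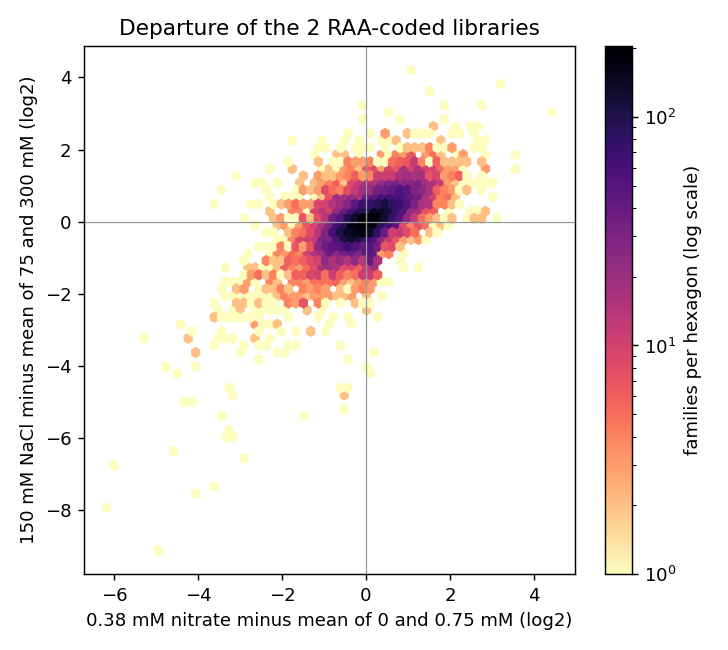
Departure of the 0.38 mM nitrate library from the mean of the 0 and 0.75 mM libraries (x axis, log2) against that of the 150 mM NaCl library from the mean of the 75 and 300 mM libraries (y axis, log2), with shading for the number of families per hexagon on a log scale. The departures lie along a rising line with r = 0.636.

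The shared control allowed the responses to nitrate limitation and to NaCl to be set side by side. In 1 model of all 10 libraries, 314 of 9012 families followed nitrate (113 higher and 201 lower as nitrate fell) and 1383 followed NaCl (935 higher and 448 lower as NaCl rose; limma-trend, adjusted p under 0.05). The counts became 13 and 114 in a model with terms for the RAA codes and for codes c3 to c6, which was added after the data were seen. Rising under both stresses were 37 families, where independent lists would share 11.7, and falling under both were 55, where independent lists would share 9.99, while 1 family went in opposite directions. In 20 simulations with no effect and the same shared control the highest overlap was 0, which follows from the few calls made without effects and sets no bound on what the shared control adds to real ones. The control is 1 library and cannot be split, so part of the excess can come from it. With the control left out, 11 families rose under both (0.891 for independent lists) and 18 fell under both (1.64), in a fit whose slopes remain linked through a common intercept, so independent lists are not its value without a shared effect. The series also share title codes, and the overlap with terms for them was added after the data were seen. With a term for the RAA codes, 62 families rose and 136 fell under both (21.7 and 27.2 for independent lists), and with terms for the RAA codes and codes c3 to c6, 1 rose and 1 fell under both (0.0138 and 0.0635).

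The slope per step of nitrate limitation differed from the slope per step of NaCl in 1769 of 9012 families (limma-trend, adjusted p under 0.05), with the slope of limitation the lower in 1180 and the higher in 589. With median-ratio scaling it was the lower in 1117 and the higher in 937 of 2054 families. By their calls in the same model, 1008 of the 1769 families followed NaCl alone, 95 followed nitrate alone, 13 followed both and 653 followed neither. Without the 600 mM library 731 families differed, and with terms for the title codes 1212 did. Family 201_c0 had the largest difference among the named families, with a slope of limitation minus slope of NaCl of -1.82 ± 0.21 (SE) log2 units per step (limma, adjusted p = 0.00056). For family 9662_c0 the difference was -0.04 ± 0.12 (limma, adjusted p = 0.861), and its value was 26.9 at 0 mM nitrate and 19.92 at 600 mM NaCl against 1.4 in the control. Across 8533 families, the slopes of the 2 series had r = 0.389 (Spearman rho 0.383), and simulated libraries with no effect and the shared control gave 0.378, with a range of 0.332 to 0.425. The simulated r is set by the weight of the control in the 2 slopes. Effects unrelated between the series would lower it, so 0.378 is not the value to compare with where effects exist. The covariance was 0.0271 against a simulated 0.00854, a difference of 0.0185. Without the control library in either series r was 0.205.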

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

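Every explanation weighed here, and every test of other orders of the libraries, was chosen after the results were seen, whereas the test of the slope difference was planned. A difference between the series in slope per step drew attention in 1769 families and in 7 of the 8 named ones. Limitation minus NaCl came to -1.65 log2 units per step for 720_c0, -1.26 for 0_c0, 1.31 for 1084_c0, -1.82 for 201_c0, -1.2 for 12126_c0, 0.96 for 63_c1 and 1.42 for 1268_c0. A difference covers both opposite and unequal slopes. Of the 1769 families, 358 had a slope above 0 under limitation and below 0 under NaCl, and 541 had the reverse. Slopes were above 0 in both series in 622 families and below 0 in both in 248. These are signs of fitted slopes, most of them not called. Both slopes passed the threshold in 0 of the 358, 1 of the 541, 5 of the 622 and 7 of the 248. Among the named families, 1084_c0 had 1298.79 at 0 mM nitrate and 2.96 at 600 mM NaCl against 5.23 in the control, and 720_c0 had 0.39 and 586.51 against 655.22. The values of 63_c1 and 1268_c0 were lower than in the control (687.63 and 196.38) both at 0 mM nitrate (7.51 and 35.33) and at 600 mM NaCl (1.81 and 0.73). The named families were picked for a slope in 1 of the series, so a difference is more probable in them than in other families.

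Other orders of the libraries were fitted to see whether chance could give as many calls. For nitrate, 2 of 100 orders drawn from 360 gave as many families as the real order, which itself gave 23, so chance order is excluded at the 5% level. The other of the 2, in which the libraries of 0 to 9 mM took ranks 2, 1, 3, 5, 6 and 4, gave 373. That order keeps the 3 lower concentrations apart from the 3 higher ones. However, 98 of the 100 orders gave 0 families and were not sorted by whether they keep this split. The count of 373 therefore cannot be credited to the split. For NaCl, 1 of all 60 orders, the real one, gave as many as its 79 families, and the highest other, with 150 and 300 mM exchanged, gave 44. For the slope difference, 1 of 100 orders, the real one, gave as many as 1769, and the highest other gave 486. For the NaCl count, whose 60 orders were all fitted, chance order is excluded at the 5% level in the main setting. For the slope difference, libraries were exchanged across both series at once, so a trend with NaCl alone would also exceed the other orders. By their calls, 1008 of the 1769 families followed NaCl alone. These orders therefore cannot show that the difference between the series is beyond chance.

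The 2 libraries with RAA codes depart from their neighbours in the same families, with r = 0.636, although the departures share no library and come from different series. The neighbours include libraries coded c3, c4 and c6, but 0.38 minus 0.75 mM nitrate (c7) alone still had r = 0.565 with the 150 mM departure, against 0.048 with 0 mM (c6) in place of 0.38 mM and -0.111 with the control in place of 150 mM, which is consistent with a batch of cultures or libraries marked by the RAA code. A trend with expression level is argued against by r = 0.617 once the median departure per level was removed. The 150 mM departure had r = 0.081 with 0.75 mM minus the 1.5 and 3 mM libraries, all outside codes c3 to c6. This argues against a state of the 150 mM NaCl culture like that at 0.75 mM nitrate. It cannot decide on a stronger nitrate limitation, because the 0.75 mM library is nearer to the control (r = 0.922) than 0 mM (0.847) or 0.38 mM (0.829). At 4-fold, 83 families lay below and 14 above the neighbours in both libraries and 0 lay above in one and below in the other. The code falls on 1 concentration of each series, so batch and concentration cannot be separated for a single family such as 52_c0 within a series.

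Of the 191 families seen at 600 mM NaCl, a set whose rule gave 0 to 3 families for each other library, 124 were above 0 at 75 mM NaCl, 129 at 300 mM, 57 at 0 mM nitrate and 21 at 0.75 mM nitrate, and 0 to 4 in the 5 others, and these 4 libraries also list fewer families at 0 overall (380, 600, 802 and 783) than the 5 others (948 to 1263). The traces also follow the title codes, with 54.1% of the set's values above 0 in the libraries coded c3, c4 and c6, beside c5 for 600 mM, against 2.44% in the 6 others, and 0 mM nitrate (c6) has more traces than 0.75 mM (c7) although it lists more families at 0. Reads carried over from the 600 mM library could give such traces, but would add the same share to every family: of 2012 families at 50 or more at 600 mM, 10 at 0 mM nitrate, 5 at 75 mM and 3 at 300 mM were above 0 yet more than 4-fold under the value that the set's share would give, which argues against it but leaves it open, because the families are few and the counting spread is unknown without the depth. A graded response to NaCl cannot be told apart from it either, because 0 of the set's families were above 0 at 150 mM while 124 were at 75 mM and 32.3% of 934 other families with a trace at 75 mM were above 0 at 150 mM, which argues against it, but the values are near the floor and the 150 mM library carries an RAA code. Reads of another source in the 600 mM library and a response that starts between 300 and 600 mM also stay open and were not tested, and without the 191 families the NaCl trend had 69 calls in place of 79.

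The 75 mM NaCl library differed from the control by 2-fold in 913 families, against 407 and 170 for 1.5 and 3 mM nitrate. A difference between the libraries coded c3 to c6 and those coded c1, c2, c7 and c8 is a candidate explanation, since 75 mM minus control had r = 0.342 with 0 mM nitrate (c6) minus the 1.5 and 3 mM libraries, and r = 0.075 with 0.75 mM (c7) in its place. The contrast of 300 with 75 mM, in which both codes are of the same set, had r = 0.263 with the same nitrate contrast. The code therefore cannot be told apart from a response that NaCl and lack of nitrate share, which stays open as the biological explanation, because every NaCl library other than the control is coded c3 to c5 or RAA.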

How the results depend on the processing

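Terms and subsets for codes c3 to c6, the fit without the 191 families, the sets separating levels, the omission of libraries from the slope difference, and the slope correlations without RAA libraries were chosen after the data were seen. The count tests planned as alternatives (DESeq2 and limma-voom) were not used, because the values are not counts, and the gene list tests were not run, because families have no gene names. No paired analysis was possible because each condition had 1 library, so the groups share a single replicate number. Of 96 alternative values of the main results, 39 lay within 1.5 times (for correlations, within the sampling interval across families) and 57 did not. In each series the trend fit without the RAA library is counted there again as the omission of that library. The cause of the differences was not tested except where fewer libraries or families were fitted. Read depth is unknown, so its limit on low families cannot be stated.

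The nitrate count of 23 became 187 with median-ratio scaling, 107 with equal totals, 120 without the 50 most abundant families, 42 with a mean value of at least 5, and 460 with 2 levels. It became 314 with all 10 libraries in 1 model, 509 with an RAA term and 13 with terms for RAA and c3 to c6. It was 0 (limma-trend) with no filter, concentration in mM, log2 concentration, pseudocount 0.1, without the RAA library and in the 4 libraries coded c1, c2, c7 and c8. Leaving out 1 library gave 0 to 220, with 220 without 0.75 mM and 0 without any other. Over these 11 settings with no call, 309 to 2464 families had an unadjusted p under 0.05.

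The NaCl count of 79 became 48 with median-ratio scaling, 10 with equal totals, 42 with no filter, 43 with a mean value of at least 5, 450 with concentration in mM, 1 with 2 levels, 48 without the 50 most abundant families and 163 without the RAA library. It became 1383 with all 10 libraries and 1846 with an RAA term, and 411 in the 3 libraries coded c3 to c5. With log2 concentration (78), pseudocount 0.1 (57), terms for RAA and c3 to c6 (114) and without the 191 families (69) it stayed within 1.5 times. Leaving out 1 library gave 0 to 203, with 0 (limma-trend; 1109 at an unadjusted p under 0.05) without 600 mM, 44 without the control, 197 without 75 mM, 163 without 150 mM and 203 without 300 mM.

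The slope difference count of 1769 ran from 731 (without 600 mM) to 2131 (without 0 mM nitrate) when 1 library was left out, and was 2054 with median-ratio scaling (937 with limitation the higher, 1117 the lower), 2227 with no filter, 2332 with an RAA term and 1212 with terms for RAA and c3 to c6. The slope correlation of 0.389 was 0.205 without the control, 0.254 without the control and the RAA libraries, 0.404 without the RAA libraries and 0.383 with a mean value of at least 5.

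For families 2-fold from the control, a pseudocount of 5 gave 1529 of 2351 at 0 mM nitrate, 1349 of 2155 at 0.38 mM, 612 of 1046 at 0.75 mM, 165 of 407 at 1.5 mM, 62 of 170 at 3 mM, 512 of 913 at 75 mM NaCl, 1321 of 2189 at 150 mM and 1286 of 2310 at 300 mM. At 4-fold the counts were 584, 599, 204, 28 and 14 from 0 to 3 mM nitrate, and 215, 590, 615 and 1069 (of 2797) from 75 to 600 mM NaCl. The NaCl set of 132 families separating 150 to 600 mM from 42 and 75 mM became 642 without the 150 mM library, where fewer libraries have to be separated.

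For the 8 named families, 154 alternative values kept the direction in each case; 87 stayed past the threshold and 67 did not, with adjusted p (limma) from 0.000762 to 0.843. Nitrate families stayed past it in 8 of 20 fits (720_c0), 8 of 19 (0_c0), 8 of 20 (1084_c0) and 9 of 20 (9662_c0), and NaCl families in 6 of 18 (201_c0), 15 of 19 (12126_c0), 16 of 19 (63_c1) and 17 of 19 (1268_c0).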

Other observations

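The comparisons in this part were chosen after the data were seen, and they describe single libraries. Shares of random lists measure the drawing of families only. They make no allowance for families that move together or for spread between cultures, so they are not p-values for a condition. The 129 families with lower values at low nitrate were set against NaCl, with the 75 mM library as reference, so that the control, by which they were picked, did not enter. At 600 mM their median log2 ratio to 75 mM was -1.11, with 76 families at least 2-fold lower and 5 at least 2-fold higher. Of 10000 random lists of the same size matched on mean expression, 0% had a median at or below it, and their median was -0.29. Relative to the control, whose high value entered their choice, the median of the same 129 families was 0.02 at 75 mM, -0.48 at 150 mM, 0.00 at 300 mM and -1.21 at 600 mM. The 99 families with higher values at low nitrate had a median of 0.12 at 600 mM against 75 mM, above 99.88% of random lists, with 20 families at least 2-fold higher and 23 at least 2-fold lower. Relative to the control, whose low value entered their choice, the medians of the 99 were 0.61 at 75 mM, 0.96 at 150 mM, 0.72 at 300 mM and 0.66 at 600 mM, with 34, 46, 40 and 41 families at least 2-fold higher.

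The families with lower values at 150, 300 and 600 mM NaCl than at 42 and 75 mM were set against nitrate with the mean of the 1.5 and 3 mM nitrate libraries as reference, since the control had entered their choice. Of the 79, 70 had a mean value of at least 1. Their median log2 ratio to that reference was -0.92 at 0 mM, -1.73 at 0.38 mM and 0.57 at 0.75 mM nitrate, where matched random lists had medians of 0.05, 0.00 and 0.11. Of 10000 such lists, 0% lay at or below the median at 0 mM and at 0.38 mM, and 100% did at 0.75 mM. The 150 mM NaCl library, which entered the choice of the set, and the 0.38 mM nitrate library both carry RAA codes. The 53 families with higher values at these NaCl concentrations had medians of 0.48, 0.52 and 0.17 at 0, 0.38 and 0.75 mM nitrate, at or above those of 99.14%, 100% and 87.16% of lists. With no minimum fold, 25.9% of families separated these levels, where chance gives 20%. Other splits of the 5 NaCl libraries into 2 and 3 gave more families with a 2-fold separation: 434 for 300 and 600 mM against the rest and 255 for 150 and 600 mM against the rest, in place of 132.

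Values lay in strict order of concentration in 142 families over the 6 nitrate libraries, 45 rising and 97 falling, where chance gives 28.1. Over the 5 NaCl libraries the number was 485, of which 287 rose and 198 fell in order, where chance gives 169.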
